A study of Arachis hypogaea with 12 samples.

How the data were processed

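Transcript levels in peanut (Arachis hypogaea) leaves were measured on 12 Agilent oligonucleotide arrays, each hybridised with a Cy3 (green) and a Cy5 (red) labelled sample. The 24 channel samples fell into 8 groups of 3: a heat-susceptible genotype, COC166, and a heat-tolerant genotype, COC041, each at 0, 12, 24 and 48 h of heat. Group and replicate number were taken from the label of the channel that held the RNA, and its time and stress condition agreed in all 24. The arrays formed a loop, in which samples of different groups were paired directly and no common reference was used. Per the labels' protocols, plants were raised in a greenhouse, the 0 h leaves were harvested untreated at 45 days after sowing, and heated plants met a maximum of 45 °C at noon. The treatment field named heat for 12 of the 18 heated samples and was absent for the other 6. The harvest field named growth chambers for 13 of the 18 heated samples but also for 2 of the 6 at 0 h, and not for the other 5 heated ones. The 12 h leaves were taken on the same day after sowing as the 0 h leaves, and the 24 and 48 h leaves 1 and 2 days later. The labels thus do not settle which leaves came from a chamber, and the hour of harvest was not given in them. RNA was isolated with a Qiagen plant kit and labelled by Agilent's linear amplification, per the labels' protocols.

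The scanner files were made with Agilent Feature Extraction 9.5, per the submitters' processing notes. The deposited mean signals and local background medians are intensity values, the brightness of the pixels in and around each spot, with no normalization per the file headers. The deposited processed signals are intensity values after background subtraction, spatial and multiplicative detrending and dye normalization, per the file headers. Spatial detrending subtracts a fitted background surface and multiplicative detrending divides by a fitted surface of brightness, and both were switched on in the 11 files that carry a parameter block. The remaining file has no such block and holds rounded values. The deposited log ratio of each spot is a log10 value, Cy5 over Cy3 of the processed signals, per the file headers. The deposited series matrix was compared with the scanner files spot by spot and held the same log10 ratios within 0.005. Its scale and direction are thus known, and nothing in it had been centred beyond the authors' dye normalization. The medians of its 12 columns, in array order, were 0.026, 0, 0, 0.007, 0, 0.01, 0.006, 0, 0.009, 0, 0.007 and 0.006. Columns of that matrix without a sample numbered 0. Deposited flags marked spots well above background, saturated spots and outliers.

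Each array held 44415 spots, of which 42998 were not controls. These carried 21499 probe names at 2 spots each, but only 17250 distinct sequences of 60 bases, because 1047 sequences had more than 1 name and 1 sequence had 181. The unit of analysis was the distinct sequence, called a probe here. All 42998 spots were described as Unknown and 0 probe names had a match in the RefSeq genes given, so the files used here pair no probe with a gene. The 30 gene lists fixed beforehand matched 0 probes. The planned list tests, camera with either correlation and fry, were therefore void and not run. Probes are identified by ID and sequence, and genome coordinates and annotation are not given in the sources used here. Many probes tile the same transcripts: 3932 shared at least 25 bases with another on the same strand. Counts of probes are not counts of genes.

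Mean signals were corrected with limma's normexp method (offset 50) using the local background medians. Log ratios were normalized within each array by loess, with control and outlier spots at weight 0, and arrays were scaled to each other by quantiles of average intensity (Aquantile). The resulting log2 values of the single channels were averaged over the spots of a probe, leaving out control and outlier spots and keeping saturated ones. A probe was tested if well above background in at least 3 of the 24 samples, which left out 961. A further 17 were left out because all their spots were outliers in a sample, and 16272 remained. All 24 samples entered 1 limma model (lmFit and eBayes) with the 8 groups, dye as covariate and array as random block (duplicateCorrelation). The correlation within arrays was 0.599, with 15 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over the probes of each comparison and a threshold of 0.05. Probes that passed are called higher or lower, and every adjusted p printed comes from limma. R 4.3.3 was used with the packages limma 3.58.1, statmod 1.5.0 and data.table (version 1.17.8).

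The comparisons were heat against 0 h in each genotype as the mean of 3 times and at each time, tolerant against susceptible at 0 h and over the heated times, and the difference of the heat responses (interaction). These, the tests, the rule for named probes and the alternatives were fixed before the data were examined, apart from those said below to have been added. Comparisons of 12 h with the mean of 24 and 48 h were added after the data were examined. The rule took the probes with the largest rise and fall among those past the threshold and well above background in at least 2 of 3 samples of a compared group. It allowed 10 each way, 5 each way for the interaction and 3 each way at single times, among probes with a gene name. Because no probe had a name, 2 each way were taken for the 5 lead comparisons and none at single times. Where every sample of a group was saturated, a fold is given as a lower bound, from means of the normalized log2 values. Such bounds remain open to dye bias, since dyes were not balanced within groups.

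Alternatives were a fit of the 12 log ratios, no dye term, a block for replicate number, a block for slide, the processed signals, no scaling between arrays, no filter, a filter of 12 samples, the series matrix, a 2-fold minimum and leaving out each sample. The processed signals replaced both background correction and loess, and the series matrix replaced the signals and took the fit of log ratios as well, so these 2 changed more than 1 choice. Alternatives added after the data were examined were probe names as units, no background correction, and leaving out the 2 arrays with the widest deposited ratios. Arrays lay on 3 slides of 4. The slide of the first array was inferred, since only 1 position was free. According to the headers of 11 files, 1 of the slides was scanned on another day. Values within each slide come from the same samples as the fit, so they are not independent of it.

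The fit and the calls were tested on simulated log2 values with the real design, 16272 probes and 200 changed probes in each comparison. Background correction, normalization, averaging of spots and the filter were not part of this test. Probes were drawn independently of each other, with correlation within arrays but none within slides or replicate numbers, so the false share may differ in the real data. Of 2410 calls, 144 were false (6%), between 3.4% and 10.3% by comparison. For heat in the susceptible genotype, 76.1% of 1.5-fold and 100% of 2-fold changes were recovered. For the interaction, 55.2% of 1.5-fold, 85.1% of 2-fold and 100% of 4-fold changes were recovered. Between 80.4% and 88.5% of the spots of a sample were well above background and between 0.1% and 2.06% were saturated. The number of arrays limits the precision. The labels do not say that replicates came from separate plants, so p-values measure the spread between these samples, which may be partly technical. A dye effect passed the threshold in 6775 probes, and dye was therefore kept in the model as planned.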

Results

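Leaf RNA of a heat-susceptible and a heat-tolerant peanut genotype was compared over a heat treatment, to find transcripts that respond to heat and to set the responses of the genotypes side by side. Each of the 8 groups, 2 genotypes at 0, 12, 24 and 48 h, held 3 samples, and 16272 probes were tested in 24 samples. No 2 samples held identical values. Correlations of log2 values over probes, which are not independent replicates, lay between 0.975 and 0.995 within groups and between 0.894 and 0.992 across groups. The first principal component, 40.7% of the variance, separated the 6 samples at 12 h, at scores of 49.1 to 74, from the other samples, at -34.4 to 6.4. The second, 26.2%, separated the 6 unheated samples, at -51 to -44.7, from the heated ones, at -2.7 to 31.9. All values below are normalised log2 signals, given as mean ± SD with n = 3 per group.

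A large part of the probes changed level between 0 h and the heated times in the susceptible genotype. No group held unheated leaves at 12, 24 or 48 h. Heat is therefore not separated from age or growth chamber in the differences called heat responses here. By the nominal times, leaves at 0, 24 and 48 h share an hour of the day and leaves at 12 h do not. Heat is thus not separated from hour of harvest at 12 h or in means that include 12 h. At 24 and 48 h this rests on the nominal times, since the labels give no hour. Over the 3 heated times, 4829 of 16272 probes (29.7%) differed from 0 h, 2570 higher and 2259 lower, and 959 of them by at least 2-fold (462 higher, 497 lower). Among probes not saturated in all samples of a group, the strongest rise was at AH31739 (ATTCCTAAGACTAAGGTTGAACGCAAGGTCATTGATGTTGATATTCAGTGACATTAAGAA), from 7.83 ± 0.72 at 0 h to 10.19 ± 0.76 at 12 h, 14.13 ± 0.88 at 24 h and 15.03 ± 0.31 at 48 h. The fitted mean rise was 42.2-fold (log2 5.40, SE 0.33, adjusted p 2.16e-09), and 9 of 9 heated samples lay above every 0 h sample. Over the alternatives that rise lay between 5.16 and 6.81 on the log2 scale. AH10800 (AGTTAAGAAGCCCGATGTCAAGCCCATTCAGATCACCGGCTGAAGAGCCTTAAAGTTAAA) rose from 9.36 ± 0.21 and was saturated in all 3 samples at 48 h. Its mean rise was at least 32.1-fold (adjusted p 1.77e-09; 9 of 9 samples), a lower bound that leaves its rank beside AH31739 unknown. The strongest fall was at AH15391 (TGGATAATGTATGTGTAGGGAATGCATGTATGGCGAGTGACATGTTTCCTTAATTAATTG), from 13.51 ± 0.28 to 8.13 ± 0.89, 9.31 ± 0.98 and 7.26 ± 0.53 (log2 -5.57, SE 0.28, adjusted p 1.42e-10; 9 of 9 samples). AH11866 (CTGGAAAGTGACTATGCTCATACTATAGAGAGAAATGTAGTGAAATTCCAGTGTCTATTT) fell by 4.64 (SE 0.27, adjusted p 8.98e-10; 9 of 9 samples). With slide as a block 4737 probes were called, and within slides 1 and 3 the called probes kept their direction in 99.9% and 94.7%, while slide 2 held no susceptible 0 h sample. The count was 3011 without susceptible 0 h replicate 2 (1500 higher, 1511 lower), 3184 with no dye term, 3317 in the fit of log ratios and 2354 in that fit of the authors' series matrix.

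In the tolerant genotype more probes passed the test. Over the heated times 7085 probes (43.5%) differed from 0 h, 4070 higher and 3015 lower, and 1301 by at least 2-fold. AH12785 (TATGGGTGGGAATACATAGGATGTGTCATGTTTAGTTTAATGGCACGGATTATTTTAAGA) showed the strongest rise among probes not saturated in all samples of a group, from 9.10 ± 0.02 to 12.98 ± 0.61, 13.06 ± 0.85 and 13.38 ± 0.19 at 12, 24 and 48 h. Its mean rise was 20.1-fold (log2 4.33, SE 0.26, adjusted p 9.04e-10; 9 of 9 samples above every 0 h sample). AH31739 rose 18.3-fold (log2 4.20, SE 0.33, adjusted p 1.59e-08; 8 of 9 samples above every 0 h sample and 9 above their mean). AH15391 again showed the strongest fall, from 13.02 ± 0.30 to 7.32 ± 0.27 at 48 h (log2 -5.07, SE 0.28, adjusted p 3.29e-10; 9 of 9 samples). AH11347 (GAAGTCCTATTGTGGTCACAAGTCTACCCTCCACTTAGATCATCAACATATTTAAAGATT) fell by 3.96 (SE 0.21, adjusted p 2.84e-10; 9 of 9 samples). The count was 7092 with slide as a block, and 89.5%, 97.1% and 99.7% of the called probes kept their direction within slides 1, 2 and 3. It was 4615 with no dye term, 5442 in the fit of log ratios and 3874 in that fit of the series matrix.

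Most probes that passed in the susceptible genotype passed in the same direction in the tolerant one. Of the 2570 higher in the susceptible genotype, 2350 (91.4%) were also higher in the tolerant genotype, where independent lists would share 642.8. Of the 2259 lower ones, 1795 (79.5%) were lower in both, where independent lists would share 418.6. Probes higher in the susceptible and lower in the tolerant genotype numbered 0, and 13 were lower in the susceptible and higher in the tolerant. Across the probes tested, the mean heat responses correlated at r = 0.899 (Spearman 0.822), against -0.071 in simulated unchanged data with the same arrays, and 78.6% had the same sign. The covariance was 0.261, against -0.001. The groups compared here shared no 0 h samples.

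**Figure D1:**
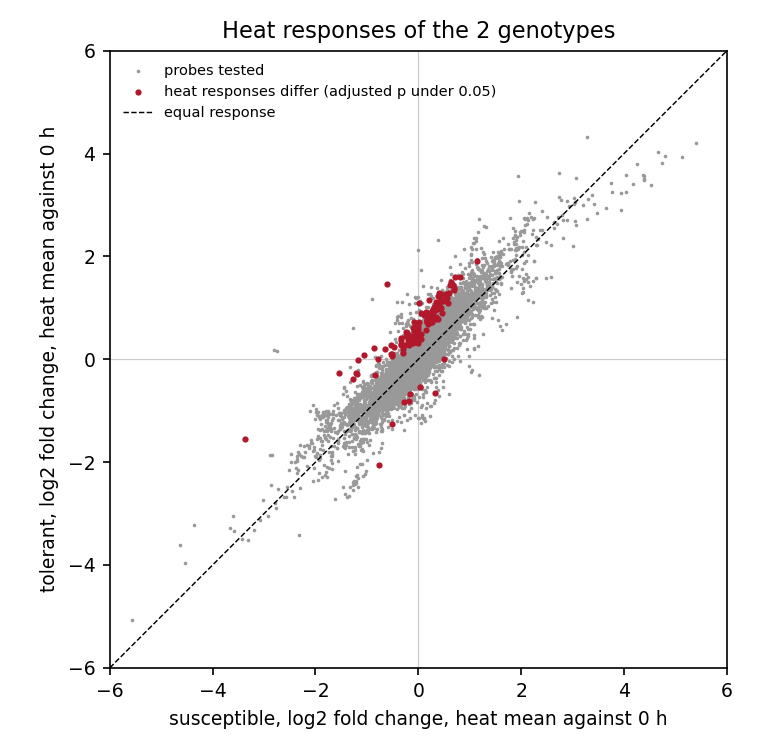
Mean heat response of each of the 16272 probes, as log2 fold change against 0 h in the susceptible (horizontal) and the tolerant genotype (vertical), with the dashed line at equal responses and red points for the 119 probes whose responses differed. Probes lie along the dashed line (r = 0.899), and 111 of the red points lie above it.

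The response depended on time. In the susceptible genotype 5230 probes differed from 0 h at 12 h (2987 higher, 2243 lower), 3978 at 24 h (1870 and 2108) and 3885 at 48 h (2125 and 1760). In the tolerant genotype 7127 differed at 12 h (4164 and 2963), 4913 at 24 h (2829 and 2084) and 5502 at 48 h (3334 and 2168). AH31739 is an example of a late response: its rise in the susceptible genotype was 2.50 on the log2 scale at 12 h, 6.63 at 24 h and 7.07 at 48 h, and 1.31, 5.48 and 5.80 in the tolerant genotype. At 12 h AH15391 fell by 5.74 in the susceptible genotype and fell by 4.88 in the tolerant.

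Probes called higher at all 3 times numbered 824 in the susceptible and 1799 in the tolerant genotype, and 778 and 971 were lower at all 3. Independent lists would share 44.8, 148.3, 31.4 and 50.6, and simulated unchanged data 0. Because the 3 times shared their 0 h samples, too few to be split, part of the excess may come from these. In the susceptible genotype 1753 probes were called higher at 12 h alone. Of these, 1487 were also higher at 12 h than at the mean of 24 and 48 h by the test of that difference. The tolerant genotype had 1840 such probes, of which 1517 passed that test. Probes called lower at 12 h alone numbered 1138 and 1595, of which 934 and 1074 passed it. Opposite calls at 12 h and at 24 or 48 h were made for 533 probes in the susceptible and 496 in the tolerant genotype.

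The 12 h responses differed from the later ones. Direct tests of 12 h against the mean of 24 and 48 h, chosen after the data were examined, called 5399 probes in the susceptible genotype and 5931 in the tolerant. Across probes the 24 and 48 h responses correlated at 0.937 in the susceptible and 0.966 in the tolerant genotype, and the 12 and 48 h responses at 0.411 and 0.461. Simulated unchanged groups with the same shared 0 h samples gave 0.451, 0.422, 0.544 and 0.551. The covariances were 0.31, 0.368, 0.169 and 0.22, against 0.011, 0.009, 0.013 and 0.013 simulated. Counts at single times moved by over 1.5 times in some alternatives: the 24 h count of the susceptible genotype was 1850 without susceptible 0 h replicate 2 and 1937 without susceptible 24 h replicate 2. Lower calls were no longer the majority there with no dye term (1109 higher, 1047 lower), from the series matrix (646 and 520), without susceptible 0 h replicate 1 (2065 and 2047) and at 2-fold or more (520 and 387), nor higher calls at 12 h at 2-fold or more (653 and 859). The count of the tolerant genotype at 24 h was 3205 without tolerant 0 h replicate 2.

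**Figure D2:**
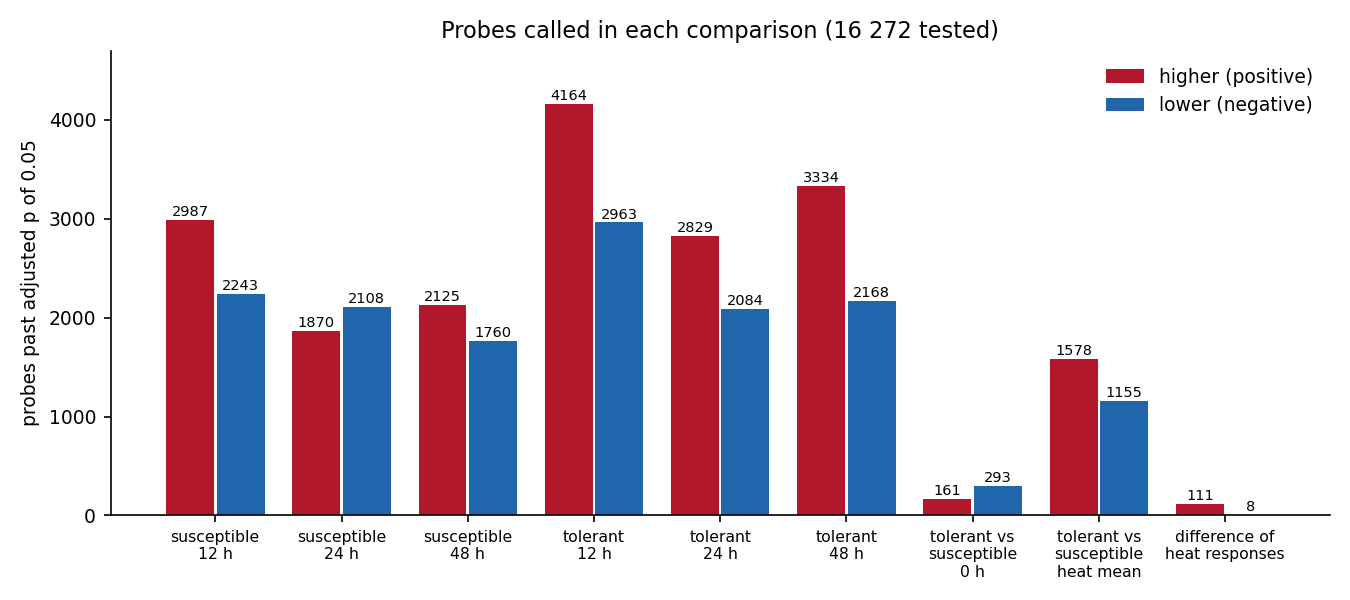
Bars give the number of probes past an adjusted p of 0.05 among 16272 tested, higher in red and lower in blue, for each heated time against 0 h, for tolerant against susceptible leaves, and for the difference of the heat responses. Heat calls range from 1760 to 4164 per direction, and 161 and 293 probes differed between genotypes at 0 h.

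Before heat, few probes passed the test between the genotypes. At 0 h 454 of 16272 probes (2.8%) differed, 161 higher and 293 lower in the tolerant genotype, and 93 by at least 2-fold. AH10374 (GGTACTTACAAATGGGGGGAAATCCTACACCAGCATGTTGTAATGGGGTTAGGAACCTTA) stood at 11.99 ± 0.06 in the susceptible and 7.13 ± 0.65 in the tolerant genotype (log2 -4.67, SE 0.22, adjusted p 2.65e-10; 3 of 3 samples below every susceptible sample). AH15083 (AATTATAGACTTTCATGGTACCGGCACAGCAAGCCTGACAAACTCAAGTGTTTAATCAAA) stood at 11.64 ± 0.27 and 7.07 ± 0.38 (log2 -4.51, SE 0.22, adjusted p 2.65e-10; 3 of 3 samples). Higher in the tolerant genotype were AH13815 (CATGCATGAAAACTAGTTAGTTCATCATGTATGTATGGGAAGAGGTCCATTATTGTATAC; log2 4.09, SE 0.68, adjusted p 0.00175) and AH25056 (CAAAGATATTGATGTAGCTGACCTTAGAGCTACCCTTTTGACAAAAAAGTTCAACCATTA; log2 3.81, SE 0.61, adjusted p 0.00131), each in 3 of 3 samples. Both lost their calls in the 2 log-ratio fits, with adjusted p up to 0.222 and 0.187, at log2 differences of 4.73 and 4.04 in the fit of log ratios and 6.67 and 5.05 from the series matrix. The count was 332 with slide as a block, with the same direction in 98.7% and 94.5% of the called probes within slides 1 and 3, while slide 2 held no susceptible 0 h sample. It was 5 in the fit of log ratios and 8 from the series matrix. It lay between 185 and 292 without any 1 of tolerant 0 h replicates 1, 2 and 3 or susceptible 0 h replicates 1 and 2, and was 763 without tolerant 12 h replicate 3.

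Under heat 2733 probes (16.8%) differed between the genotypes, 1578 higher and 1155 lower in the tolerant one, but only 179 by at least 2-fold (84 and 95). Each side held 9 samples here and 3 at 0 h, so the tests differ in precision. AH10374 again differed most, with a log2 difference of -4.63 (SE 0.12, adjusted p 4.08e-15; 9 of 9 samples), and its own mean heat response did not pass the test in either genotype (adjusted p 0.191 and 0.197), though at 12 h it fell by 0.56 in the susceptible (adjusted p 0.036). AH20453 (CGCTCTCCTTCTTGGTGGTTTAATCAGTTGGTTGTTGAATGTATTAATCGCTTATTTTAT) was also lower in the tolerant genotype (log2 -3.47, SE 0.13, adjusted p 2.6e-12; 9 of 9 samples). AH16608 (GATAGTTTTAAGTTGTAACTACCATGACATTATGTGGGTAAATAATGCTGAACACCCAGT) was 8.29-fold higher (log2 3.05, SE 0.28, adjusted p 2.6e-07; 9 of 9 samples above the susceptible mean and 5 above every susceptible sample). There, susceptible 24 h replicate 2 stood at 10.08 and the other 8 heated susceptible samples at 6.62 to 7.19. AH36955 (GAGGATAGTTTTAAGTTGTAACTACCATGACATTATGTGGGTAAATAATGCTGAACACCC), which overlaps AH16608, was 6.72-fold higher (log2 2.75, SE 0.24, adjusted p 1.72e-07; 9 and 8 of 9 samples). Over the alternatives the log2 difference ranged from 2.84 to 4.69 at AH16608 and from 2.57 to 4.74 at AH36955. Of the probes that differed at 0 h, 132 of the 161 higher ones and 171 of the 293 lower ones differed in the same direction under heat, where independent lists would share 15.6 and 20.8. The count was 2287 with slide as a block, with the same direction in 81.1%, 93.8% and 97.8% within slides 1, 2 and 3. It was 1747 without susceptible 12 h replicate 3, 1106 with no dye term, 1205 in the fit of log ratios, 977 from the processed signals and 500 from the series matrix, and most calls were no longer higher ones with no dye term (530 higher, 576 lower) and from the processed signals (486 and 491).

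**Figure D3:**
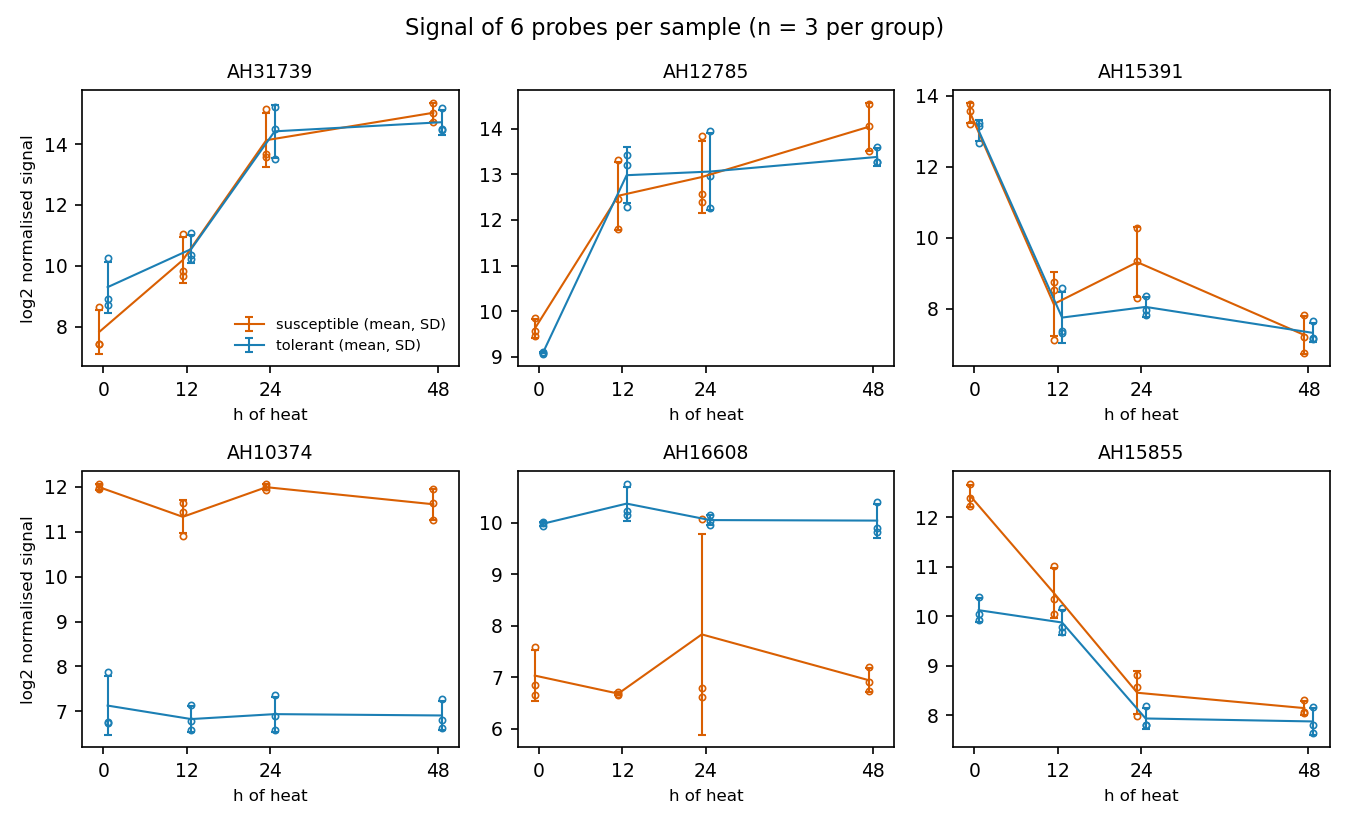
Log2 normalised signal of 6 probes against h of heat, with a circle per sample and lines and bars for mean and SD of the 3 samples of a group, susceptible in orange and tolerant in blue. AH31739 and AH12785 rose and AH15391 fell in both genotypes, AH10374 and AH16608 differed between genotypes, and AH15855 started at 12.43 in the susceptible and 10.12 in the tolerant genotype.

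Few probes passed the test of a difference in heat response between the genotypes. At an unadjusted p under 0.05 in limma there were 2016. The fit recovered 55.2% of 1.5-fold simulated changes, so smaller differences may have been missed. The test of the difference called 119 of 16272 probes, 111 with a more positive response in the tolerant genotype and 8 with a more negative one, at a median size of 0.64 on the log2 scale. Of the 111, 46 were called higher under heat in both genotypes, 39 higher in the tolerant and not called in the susceptible, 10 higher in the tolerant and lower in the susceptible, 11 lower in the susceptible and not called in the tolerant, and 5 lower in both. At 0 h 53 of them were called lower in the tolerant genotype. AH15855 (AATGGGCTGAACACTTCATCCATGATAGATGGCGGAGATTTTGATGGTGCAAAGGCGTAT) fell by 3.37 in the susceptible and fell by 1.55 in the tolerant genotype, a difference of 1.82 (SE 0.20, adjusted p 0.000479; 9 of 9 tolerant samples above the susceptible mean response). It stood at 12.43 ± 0.22 and 10.12 ± 0.24 at 0 h, and at 8.14 ± 0.14 and 7.87 ± 0.27 at 48 h. AH14316 (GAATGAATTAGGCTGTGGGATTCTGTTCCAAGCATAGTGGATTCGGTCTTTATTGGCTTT) rose by 1.46 in the tolerant genotype and did not pass the test in the susceptible (log2 -0.61), a difference of 2.07 (SE 0.43, adjusted p 0.0394; 9 of 9 samples). Without susceptible 24 h replicate 2 that difference was 1.25. AH17643 (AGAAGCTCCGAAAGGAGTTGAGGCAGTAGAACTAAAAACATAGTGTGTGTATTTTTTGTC) fell by 0.77 in the susceptible and fell by 2.05 in the tolerant genotype (difference -1.28, SE 0.24, adjusted p 0.0253; 9 of 9 samples). It stood at 8.04 ± 0.33 and 9.34 ± 0.68 at 0 h, and at 7.09 ± 0.19 and 7.23 ± 0.22 at 48 h. In limma the genotypes differed at this probe at 0 h (log2 1.15, adjusted p 0.00517). Under heat the difference did not pass (-0.13, adjusted p 0.56). AH32037 (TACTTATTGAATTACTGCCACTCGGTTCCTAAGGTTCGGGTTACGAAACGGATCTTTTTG) fell by 0.65 in the tolerant genotype and stood at a log2 change of 0.33 in the susceptible, which did not pass (difference -0.98, SE 0.21, adjusted p 0.0394; 9 of 9 samples). With slide as a block only AH15855 of these 4 passed (1.78, SE 0.20, adjusted p 0.00251). AH14316 (1.99, SE 0.47, adjusted p 0.0826), AH17643 (-1.26, SE 0.27, adjusted p 0.066) and AH32037 (-0.98, SE 0.21, adjusted p 0.066) did not, at similar sizes but with 13 residual degrees of freedom in place of 15. The replicate block ended the calls of AH14316 (1.91, SE 0.43) and AH17643 (-1.27, SE 0.28; adjusted p 0.069 each). Within slides 1 and 3, from means of the samples and times that each held, the differences were 1.47 and 0.96 at AH15855 and 1.16 and 0.88 at AH14316. They were -0.71 and -1.95 at AH17643 and -1.2 and -0.86 at AH32037. The count was 42 with slide as a block (38 positive, 4 negative), with the same direction in 94.1% and 98.3% of the called probes within slides 1 and 3. It depended on single samples, from 1 without susceptible 0 h replicate 2, tolerant 0 h replicate 2 or tolerant 0 h replicate 3 to 489 without tolerant 12 h replicate 3, and limma's fit of the log ratios called 0 (1063 at an unadjusted p under 0.05) with 4 residual degrees of freedom, a fit that recovered 4.5% of 1.5-fold and 58.2% of 2-fold simulated changes.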

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

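The tests of scaling between arrays and of leaving out single samples and the counts of splits were chosen after the results were seen, and the other tests here before. The test of the difference between the heat responses of the genotypes drew attention to 119 probes and to 4 named ones. Differences, tolerant minus susceptible on the log2 scale, were 1.82 at AH15855 (adjusted p 0.000479; 9 of 9 samples), 2.07 at AH14316 and -0.98 at AH32037 (adjusted p 0.0394 each; 9 of 9 samples), and -1.28 at AH17643 (adjusted p 0.0253; 9 of 9 samples). Without susceptible 24 h replicate 2, which stood at 8.57 at AH14316 beside 11.79 and 11.7 in the other replicates, the difference at that probe was 1.25 (adjusted p 0.000114, up to 1 over the alternatives). With slide as a block AH15855 passed (1.78, adjusted p 0.00251), and AH14316 (1.99, SE 0.47 in place of 0.43, adjusted p 0.0826), AH17643 (-1.26, SE 0.27 in place of 0.24, adjusted p 0.066) and AH32037 (-0.98, SE 0.21 in both, adjusted p 0.066) did not. Their sizes moved by less than 1 SE, while the residual degrees of freedom fell from 15 to 13. Of 100 splits of the samples, 2 gave at least 119 calls, the real split included. The splits exchanged genotype labels within each time, so differences between the genotypes enter them and they do not decide on chance. With slide as a block the same splits gave 42 calls for the real one and 125 for the highest other, and with the replicate block 38 and 90, again 2 of 100 splits each. The highest other split without a block gave 183 calls. It was the same split in all 3 and exchanged most genotype labels under heat and none at 0 h. Such an exchange carries differences between the genotypes into the interaction. No group had the 4 samples that the search for outlying samples needs.

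Of the 119 probes, 111 (93.3%) responded more positively in the tolerant genotype. The tables argue against single samples, scaling and signal differences between arrays as technical explanations: at an unadjusted p under 0.05, the share of positive differences was at least 72.2% leaving out single samples (947 of 1312 without susceptible 0 h replicate 1; 77.4% with all samples), and with no scaling between arrays 86.6% of the calls were positive. Shares of the calls themselves were not used for single samples, since some of these fits made only 1 or 2. The fit of log ratios, which differences between arrays do not enter, gave the 119 probes a median ratio of 1 to these responses, though it called 0 of them. Of the 119, 96.6% were well above background in all 24 samples (87.5% of those tested). This met what had been written against probes close to background, but that flag is also passed at low signals. AH15083, a positive call (1.14), passed it in 3 of 3 tolerant samples at 48 h at a mean of 6.89. AH16608 passed it in 2 of 3 susceptible samples at 12 h at 6.68. A fall may be cut short at such levels, so closeness to background stays open for some probes. A stronger upward response of the tolerant genotype may be biological, as a hypothesis found and tested on the same data. Dye was not among these explanations and stays open, since dyes were not balanced within groups. The count was 1 with no dye term and 4 from the processed signals. At an unadjusted p under 0.05 in limma, 66.8% and 69.1% of the differences were positive in these 2 fits. What stays open as well is the 0 h state, since 53 of the 111 were lower in the tolerant genotype at 0 h and the count was 1 or 2 without either of susceptible 0 h replicates 1 and 2 or tolerant 0 h replicates 2 and 3. Age changed with heat in both genotypes, the labels leave the chamber unclear, and the effect of either was not tested.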

How the results depend on the processing

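The alternatives with probe names as units, with no background correction and without the 2 widest arrays, and all alternatives for 12 h against later times, were chosen after the data were examined. Counts below follow the order susceptible heat mean, tolerant heat mean, susceptible at 12, 24 and 48 h, tolerant at 12, 24 and 48 h, genotypes at 0 h, genotypes under heat, interaction, and 12 h against later in the susceptible and tolerant genotype. No filter, a filter of 12 samples, probe names as units and no background correction moved none of the 13 counts by over 1.5 times. A 2-fold minimum, which removes calls by construction, gave 959, 1301, 1512, 907, 1097, 2116, 1128, 1312, 93, 179, 8, 1434 and 1546. The authors' series matrix, in the fit of log ratios and thus with 2 choices changed, gave 2354, 3874, 2650, 1166, 1593, 3974, 1478, 2111, 8, 500, 0, 2512 and 2659, the interaction with 458 at an unadjusted p under 0.05 in limma. For the settings that follow, only counts moved by over 1.5 times are given. The fit of log ratios, which leaves out differences between arrays, gave 2553 and 1811 for the susceptible genotype at 24 and 48 h, 3122 for the tolerant at 24 h, 5 at 0 h, 1205 under heat and 0 for the interaction. No dye term gave 3184 and 4615 for the heat means, 2156 and 2463 for the susceptible at 24 and 48 h, 2877 and 3175 for the tolerant at 24 and 48 h, 137 at 0 h, 1106 under heat and 1 for the interaction. The processed signals gave 2068 for the susceptible at 24 h, 114 at 0 h, 977 under heat and 4 for the interaction. No scaling between arrays gave 776 at 0 h and 216 for the interaction, and the slide block 42 for the interaction. Without the 2 widest arrays, thus with fewer samples, the counts were 2297 for the susceptible at 48 h, 4523 for the tolerant at 12 h, 256 at 0 h and 25 for the interaction. The fits of log ratios and of the series matrix had 4 residual degrees of freedom in place of 15, and in simulated data the fit of log ratios recovered 4.5% of 1.5-fold changes for the interaction and 3% at 0 h, where the single-channel fit recovered 55.2% and 52.2%, so low power accounts for part of its lower counts. For the other settings, beyond what a stricter rule or fewer samples bring, the cause was not tested.

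The replicate block gave 38 for the interaction (32 positive and 6 negative), of which 33 were among the 119, and moved no other count by over 1.5 times. The numbers are not known to pair samples. Deviations correlated at 0.213 on average within a number (-0.343 to 0.657) and at -0.123 otherwise. Of 24 samples, 21 correlated best with their own number. Most samples of a number shared a slide, a possible cause.

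Leaving out 1 sample at a time gave ranges of 3011 to 5128 for the susceptible heat mean, 1850 to 4446 for the susceptible at 24 h, 3205 to 5517 for the tolerant at 24 h, 185 to 763 at 0 h, 1747 to 3160 under heat and 1 to 489 for the interaction. The other 7 counts stayed within 1.5 times. Lowest were the first and second without susceptible 0 h replicate 2, and the second was 1937 without susceptible 24 h replicate 2. Lowest for the tolerant at 24 h was the fit without tolerant 0 h replicate 2, and under heat the fit without susceptible 12 h replicate 3. At 0 h the count was 292, 185 and 218 without tolerant 0 h replicate 1, 2 or 3, 258 and 217 without susceptible 0 h replicate 1 or 2, and 763 without tolerant 12 h replicate 3. The interaction count was 2 and 1 without susceptible 0 h replicate 1 or 2, and 30, 1 and 1 without tolerant 0 h replicate 1, 2 or 3. It was 10 and 70 without susceptible 12 h replicate 1 or 3, 181 without susceptible 24 h replicate 2, and 76 and 237 without susceptible 48 h replicate 1 or 3. It was 238 and 489 without tolerant 12 h replicate 2 or 3, 19 and 42 without tolerant 24 h replicate 2 or 3, and 75 and 25 without tolerant 48 h replicate 1 or 3.

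The correlation of the heat responses was 0.878 from the processed signals, 0.863 from the series matrix, 0.879 without the 2 widest arrays, and 0.859 to 0.909 leaving out single samples, against 0.899. Of 720 refits of the named probes, 670 kept direction and call, 50 kept direction but lost the call, and 0 turned direction. AH14316 and AH32037 lost their interaction calls in 16 of 36 alternatives each, AH17643 in 12 and AH15855 in 2, the fits of log ratios and of the series matrix. The differences in these 2 fits were 1.84 (SE 0.16) and 1.82 (SE 0.36) at AH15855, -1.3 and -1.48 at AH17643, 2.47 and 2.6 at AH14316 and -1.06 and -1.19 at AH32037. Beside these 2 fits, no dye term, the processed signals and the slide block ended the calls of AH14316, AH32037 and AH17643, the replicate block those of AH14316 and AH17643, and leaving out the 2 widest arrays those of AH14316 and AH32037. Each of these 3 also lost its call without susceptible 12 h replicate 1, susceptible 0 h replicate 1 or 2, tolerant 0 h replicate 2 or 3 or tolerant 24 h replicate 2. AH14316 did so without susceptible 12 h replicate 3, tolerant 24 h replicate 3 or tolerant 48 h replicate 3 too, and AH32037 without susceptible 48 h replicate 1 or 3, tolerant 0 h replicate 1 or tolerant 48 h replicate 1. AH13815 and AH25056 lost their 0 h calls in the fits of log ratios and of the series matrix, and the other named calls were lost in none of 36. No alternative scaling moved the median of the probes by over 0.1 or the share of higher calls by over 10 points. Between 80.4% and 88.5% of spots per sample were well above background, which limits what can be said of the rest.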

Other observations

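The hour of harvest, the reading of spots above background at 12 h, the direction of opposite-strand pairs with both probes called, the counts of splits, the comparison of genotype-parting probes and the share of tolerant RNA were chosen after the results were seen, and the other tests here before. Although no probe has a gene name, the 60 bases of some encode short peptides typical of known protein families, and such a match is no annotation. Of 13 probes that encode a stretch conserved in the chlorophyll a/b binding proteins of the light-harvesting antenna, 8 were lower under heat in both genotypes (11 in the susceptible, 8 in the tolerant) and 0 higher. Their median log2 changes in the susceptible genotype were -1.61 at 12 h, -0.41 at 24 h and -0.84 at 48 h, and in the tolerant -1.27, -0.27 and -0.55, while 1 of the 13 went the other way at 12 h (1.49 and 1.28). Of 6 probes that encode stretches of ubiquitin, the protein that tags others for degradation, 6 were higher in both genotypes, with medians of 1.11 and 1.14. Both counts met what had been written down for heat lowering the first family and raising the second, so transcripts of these families may have responded to heat. The median falls of the first family were largest at 12 h. These counts rest on means that include 12 h, so they cannot tell heat apart from age or from the hour of harvest. The labels do not give that hour. The same sequence stretches read on the opposite strand gave 1 and 2 matches, and overlapping probes within a family are not independent.

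A further 5 probes encode the end shared by cytosolic HSP70 and HSP90 chaperones, which help proteins fold. Of these, 2 were called higher in both genotypes and 4 in the tolerant (medians 0.11 in the susceptible and 0.69 in the tolerant). A low count of such calls had been written down as evidence against a rise, but a missed threshold does not show that values did not rise. The fitted changes of all 5 were positive at 24 and 48 h in both genotypes, but at 12 h in the susceptible 3 of them were negative (-0.28, -0.45 and -0.83) and called lower than later, with mean responses of 0.11, 0.03 and 0.03 that did not pass. The 2 called in both genotypes, AH27541 and AH24765, overlap. They rose by 0.99 and 1.18 in the susceptible and by 1.38 and 1.45 in the tolerant genotype. Whether the class as a whole rose stays open. The responses of 0 of the 5 differed between the genotypes by the test of the difference. The single probe that matched the stretch searched for small heat shock proteins was called higher over the heated times in both genotypes. It changed by 1.39, 5.36 and 6.39 on the log2 scale at 12, 24 and 48 h in the susceptible genotype and by 0.64, 4.22 and 5.82 in the tolerant. The search covered only that stretch, so other probes of the family, among them the strongest risers above, could have been missed. A single probe matched the actin end, with changes of -0.87, 0 and 0.22 at 12, 24 and 48 h in the susceptible genotype and -0.96, -0.15 and 0.13 in the tolerant, so it was lower mainly at 12 h. The peroxisome end matched 33 probes, the prenylation end 17 and the ER retention end 1, against 34, 10 and 1 on the opposite strand, too close to chance to be read. Calmodulin, histone, metallothionein and zinc finger stretches matched 0 probes.

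Probes that overlap on opposite strands made 1169 pairs. If both reported 1 transcript unit, their heat responses would correlate, but r was 0.12 in the susceptible and 0.09 in the tolerant genotype, against 0.95 and 0.93 for 12107 pairs on the same strand and -0.02 for random pairs in the susceptible. An r this low had been written down as evidence against a shared unit. These pairs changed little, however. In the susceptible genotype both probes were called in 15 of them, against 99 random pairs, and only 1 probe in 170, against 503. A low r may come from that as well, so it does not decide. Of the pairs with both probes called, 15 of 15 went in the same direction in the susceptible and 27 of 37 in the tolerant genotype (random pairs 50 of 99 and 114 of 228). These pairs are not independent, as they lie in 7 and 24 separate stretches (7 and 16 with only pairs in the same direction). In 170 and 329 pairs only 1 probe was called, so a shared unit stays open.

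Leaves at 12 h stood apart from the other samples. The share of spots well above background was not lower there, a median of 86.2% in the 6 samples at 12 h (85.2% to 88.5%) beside 80.4% to 88.5% in the other 18, but it does not measure the integrity of RNA, so poorer RNA stays open. The hour of the day at harvest could also set 12 h apart from 0, 24 and 48 h, which share an hour by the nominal times. It was given in 0 labels, so time of day and time in heat cannot be told apart at 12 h. An early stage of the heat response stays open beside it, untested.

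The deposited log ratios of 2 arrays spread wider than those of the other 10, with interquartile ranges of 1.98 and 2.03 on the log2 scale against 0.51 to 0.96. These held susceptible 48 h replicate 1 with tolerant 0 h replicate 1, and tolerant 12 h replicate 2 with susceptible 0 h replicate 3. Noisier spots alone are argued against: the SD between the 2 spots of a probe in the scanned ratios was 0.24 and 0.25 there and 0.11 to 0.26 on the others. The array at 0.26 had an interquartile range of only 0.85 in its deposited ratios. The remaining arrays lay at 0.2 or lower, so noise may have contributed. In the deposited ratios that SD was 4.37 and 3.68 times the scanned one, and the Cy5 detrending surface was flat on both (SD 0) while their Cy3 surface was not (SD 1.01 and 0.85; Cy5 0.53 to 1.21 on the others). The scanned ratios spread by 0.75 and 0.92 there and by 0.38 to 0.73 on the others, so these 2 arrays stayed the widest by a smaller margin. Detrending of 1 channel alone is therefore a candidate explanation for part of the spread, and no biological one was tested.

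For the heat means, 1 of 100 splits of the samples, the real one, gave as many calls as the 4829 in the susceptible genotype. The same held for the 7085 in the tolerant. A random grouping of these samples would thus rarely give as many calls. Chance differences between plants are not excluded, since the labels do not say that replicates came from separate plants. The highest other splits gave 2954 and 6485, the latter with the 3 samples at 12 h as the single group, which points to a structure of the samples. For genotypes under heat 1 of 100 splits, the real one, gave as many calls (2733, highest other 1317), with the same limit. For 12 h against later, 1 of 84 splits, the real one, gave as many calls in the susceptible (5399, highest other 2868) and in the tolerant genotype (5931, highest other 3114), but that comparison was chosen from how these samples grouped, so their splits do not test it. The 6 single times (3885 to 7127 calls) and the genotypes at 0 h (454) allow 10 splits, too few for a share under 0.05, and the highest other split gave 1 call for the susceptible at 24 and 48 h and 0 for the rest.

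Susceptible 24 h replicate 2 differed from its group at probes that part the genotypes. At 3 of 3 probes higher in the tolerant genotype, chosen without its group and by a gap of at least 1 on the log2 scale, it lay nearer the tolerant samples, and at 0 of 4 probes higher in the susceptible. In susceptible 24 h replicates 1 and 3 none of the 7 did. For samples of other groups no probe higher in the tolerant genotype met that gap, so they offer no comparison there. Tolerant RNA mixed into the sample would need a share of 0.84 to 1.02 at those 3 probes, 2 of which overlap, but of -0.49 to 0.34 at the other 4, and a first bound on the gap of these shares did not decide. At a share of 0.84 the other 4 would have stood lower by 1.6 to 2.57 on the log2 scale than they did, beyond the range of 0.14 to 0.82 between the 3 samples of the group, which argues against such a mix as the source. RNA from elsewhere and a difference between the plants sampled stay open, untested. At AH16608 the 3 susceptible samples at 24 h stood at 6.79, 10.08 and 6.62, and at AH13815 at 7.41, 11.25 and 6.67.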
